A study of Homo sapiens with 8 samples.

How the data were processed

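The series measured dimethylation of lysine 4 of histone H3 (H3K4me2) by chromatin immunoprecipitation and sequencing (ChIP-seq) in RD, an established human rhabdomyosarcoma cell line. Cells were transfected with a small interfering RNA (siRNA) against LSD1 or with a control siRNA. Per the labels' protocols, the medium was changed after 8 hours, the cells were harvested 96 hours after transfection, and chromatin was released with a douncer and sonicated. The 8 samples are 4 ChIP libraries and 4 input libraries, with 2 replicates of each siRNA in each kind. The submitters call the replicates biological. The input libraries were not analysed here.

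For each ChIP library the authors deposited a peak list, and for each siRNA a list of the pooled replicates. How the replicates were pooled is not given in the sources used here. Per the submitters' processing notes, the reads were aligned with Bowtie to the hg19 build. The version of the aligner is not given in the sources used here. The peak names in the deposited lists carry the name of MACS, whose version and settings, and whether the input libraries served as its control, are not given in the sources used here. Each deposited peak has a start, an end and a score, which is the authors' own value. From the values, with a minimum of 50 in 5 of the 6 lists and of 50.01 in the other, the score looks like minus 10 times the base-10 logarithm of the peak's p-value. The score was used only to describe, rank and filter peaks within a list. The lists give no read depth. The number of reads behind each list is therefore unknown, and a longer list can come from deeper sequencing or a better precipitation as well as from more marked sequence.

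Peaks on chromosomes 1 to 22 and X were analysed. Peaks on chromosome Y and on unplaced contigs were left out, which removed between 3 and 26 peaks per library list and 78 and 85 peaks from the pooled lists. Coordinates are hg19 and counted from 1. The gene table at hand was on another build, and no gene annotation of hg19 was used here. As laid down before the data were examined, 10-kb windows took the place of genes and promoters, and regions are named by coordinates and cytoband. The cytobands of hg19 came with the R package circlize 0.4.16. The 21 gene lists that had been fixed for adhesion, muscle, matrix, homeobox and other genes were not tested, and neither were promoter shares.

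Peaks of the 4 libraries that overlapped by at least 1 bp were merged into regions. A region was gained when both siLSD1 libraries and neither siCtrl library had a peak in it, and lost in the reverse case. The same counts were made for the 2 other ways to split the 4 libraries into pairs. For lists of equal length, the 33878 top-scoring peaks of each library list were taken, which is the length of the shortest list. Totals per library were compared by a two-sided exact permutation test, which with 2 libraries against 2 cannot give a p below 0.333. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. Chromosomes, and bands with at least 50 regions, were tested for gained or lost regions with a two-sided Fisher's exact test against all other regions, with Benjamini-Hochberg adjustment. That test treats regions as independent and compares these 4 libraries.

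For breadth, the kilobases covered by peaks in each 10-kb window were compared with limma 3.58.1 (trend and robust options, statmod 1.5.0, R 4.3.3). Windows with at least 0.5 kb covered in at least 2 libraries were tested, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. On simulated data with the spread of these libraries, limma called 0 of 100 windows shifted by 2 kb and 0 of 100 shifted by 1 kb among 43372 windows, with 0 false calls. Building of regions was tested on simulated lists and recovered 120 of 120 gained and 40 of 40 lost regions. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

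The regions named are the 12 gained and the 12 lost with the highest score in the pooled list of their siRNA, among those found only in that pooled list. Alternatives were the upper 50% of each list by score, equal numbers of peaks, an overlap of 50% of the shorter peak, merging across gaps up to 1000 bp, a replicate block, other scaling and filters in limma, and leaving out each library. Single siCtrl libraries set against single siLSD1 libraries, shorter equal lists, lists without chromosome X, 5-kb and 25-kb windows, leaving out libraries from the list totals, and 20 cytobands known for gene clusters, with all peaks and with equal numbers, were added after the data were seen.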

Results

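H3K4me2, a histone mark of promoters and enhancers, was mapped in RD rhabdomyosarcoma cells after knockdown of LSD1 and after transfection of a control siRNA, with 2 biological replicates each. LSD1, the product of KDM1A, removes methyl groups from mono- and dimethylated lysine 4 of histone H3. The study's title places the question in the adhesion of these cells. The library lists held 33878 and 44831 peaks for siCtrl replicates 1 and 2, and 50587 and 49611 peaks for siLSD1 replicates 1 and 2. These peaks covered 70.1, 94.1, 96.9 and 104 Mb, or 2.31%, 3.10%, 3.19% and 3.44% of chromosomes 1 to 22 and X. Median peak width was 1753 and 1690 bp in the siCtrl lists and 1575 and 1700 bp in the siLSD1 lists. The knockdown itself was not measured in these data. Band 1p36.12, which carries KDM1A among many other genes, had 169 and 208 kb under peaks in the siCtrl libraries and 238 and 255 kb in the siLSD1 libraries, and these values do not check the knockdown.

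The first comparison asked whether cells given the siRNA against LSD1 had more marked sequence. Both siLSD1 libraries had more peaks and more covered sequence than both siCtrl libraries. The mean was 50099 ± 690.1 peaks (SD, n = 2) after siLSD1 and 39354.5 ± 7745 (SD, n = 2) after siCtrl, a ratio of 1.27. Covered length was 101 ± 5.33 Mb (SD, n = 2) and 82.1 ± 16.95 Mb (SD, n = 2), a ratio of 1.23. The exact two-sided permutation p was 0.333 for both measures, the smallest that 2 libraries against 2 allow. The difference in covered length of 18.5 Mb was 6.54 Mb without siCtrl replicate 1, whose list was the shortest, and 30.5 Mb without siCtrl replicate 2. The difference of 10744.5 peaks was 5268 without siCtrl replicate 1 and 16221 without siCtrl replicate 2.

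Many marked regions were shared by all libraries. Of 58952 merged regions, 26653 (45.2%) had a peak in each of the 4 libraries, and these common regions had a median width of 2789 bp. The broadest of these lay in band 7p15.2, the band of the HOXA homeobox cluster, at chromosome 7 from 27199276 to 27228798. It had 28.6 ± 0.319 kb under peaks (SD, n = 2) after siCtrl and 29.2 ± 0.179 kb (SD, n = 2) after siLSD1. In 19q13.2, a region of chromosome 19 from 39137479 to 39164081 had 21.5 ± 1.36 kb under peaks after siCtrl and 25.6 ± 0.211 kb after siLSD1. In 7q32.3, a region of chromosome 7 from 130584101 to 130608114 had 19.4 ± 0.202 kb and 23.8 ± 0.0806 kb in the same order. In 1q22, a region of chromosome 1 from 155936053 to 155954429 went the other way, with 18.3 ± 0.0438 kb after siCtrl and 17.4 ± 0.363 kb after siLSD1. No test was run on single regions. Over all common regions, the mean breadth was 2457 and 2790 bp in the siCtrl libraries and 2739 and 2897 bp in the siLSD1 libraries, so that siLSD1 replicate 1 lay below siCtrl replicate 2. Both siLSD1 libraries were broader than both siCtrl libraries in 8077 common regions (30.3%) and narrower in 2564 (9.62%). Libraries with no systematic difference in breadth would give 16.7% each. Splitting the libraries by replicate number gave 9302 regions broader in both replicates 2 and 1195 narrower, so the spread between replicates was as large. The remaining split gave less, with 3806 regions (14.3%) broader in both siCtrl replicate 2 and siLSD1 replicate 1, and 1639 (6.15%) narrower. In every split the pair that held siCtrl replicate 1, the library of lowest mean breadth, was more often the narrower.

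The second comparison asked where the mark appeared or disappeared. With all peaks, 4107 regions were gained after siLSD1 and 615 were lost, a ratio of 6.68. Gained and lost regions were narrow and of low score. Their median widths were 1424 and 1390 bp, and a gained region's median score percentile was 24.1 and 23.8 in the lists of siLSD1 replicates 1 and 2. Of the gained regions, 1002 (24.4%, exact 95% interval 23.1 to 25.7%) lay within 5 kb of a common region, against 126 of the lost regions (20.5%, 17.4 to 23.9%). Light-staining cytobands, which are rich in genes, held 55.8% of gained regions (54.3 to 57.3%), 56.6% of lost regions (52.6 to 60.5%) and 60.3% of common regions (59.8 to 60.9%). With 33878 peaks per list, 1376 regions were gained and 1433 lost, so the excess of gained regions was not kept, and the ratio was 0.960. This cut removed peaks of the longer lists only. A region could then count as lost although a full siLSD1 list had a peak there. Without siCtrl replicate 1 the counts were 4607 gained and 4079 lost, a ratio of 1.13. They were 10861 and 1389 without siCtrl replicate 2, 9604 and 1351 without siLSD1 replicate 1, and 8860 and 1401 without siLSD1 replicate 2, where a single library stood for its group and the rule for that group was looser by construction.

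Regions that set the siRNA groups apart were more numerous than those of the other splits at both list lengths. With all peaks, the 4722 gained and lost regions compared with 2527 regions that set replicates 1 apart from replicates 2. The remaining split, siCtrl replicate 1 with siLSD1 replicate 2 against the others, gave 1786. With equal numbers of peaks the 3 counts were 2809, 1603 and 1057. These are 3 splits in all, too few for a test. With all peaks, the siRNA split also set both longer lists against both shorter ones, and 4107 of its 4722 regions were called only in the longer lists. The higher count can therefore come from list length. Overlap of covered sequence separated the groups only in part. With all peaks, siCtrl replicate 2 shared 67.6% and 68.8% of the joint covered length with siLSD1 replicates 1 and 2 but 66.3% with siCtrl replicate 1. The siLSD1 replicates were the most alike pair at 69.9%, and siCtrl replicate 1 shared only 60.2% and 57.8% with siLSD1 replicates 1 and 2. With equal numbers of peaks, siCtrl replicate 2 and siLSD1 replicate 2 were the most alike pair at 70.9%, against 70.4% between the siCtrl and 70.6% between the siLSD1 replicates. The other pairs across the groups were lower, at 68.5% for siCtrl replicate 2 with siLSD1 replicate 1, and at 64.7% and 63.1% for siCtrl replicate 1. Of the 1376 regions gained with equal numbers, 631 (45.9%) were also gained with all peaks, and 264 of the 1433 lost regions (18.4%) were also lost with all peaks. In the full lists, the rest lay in merged regions that also held a peak of the other group.

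**Figure D1:**
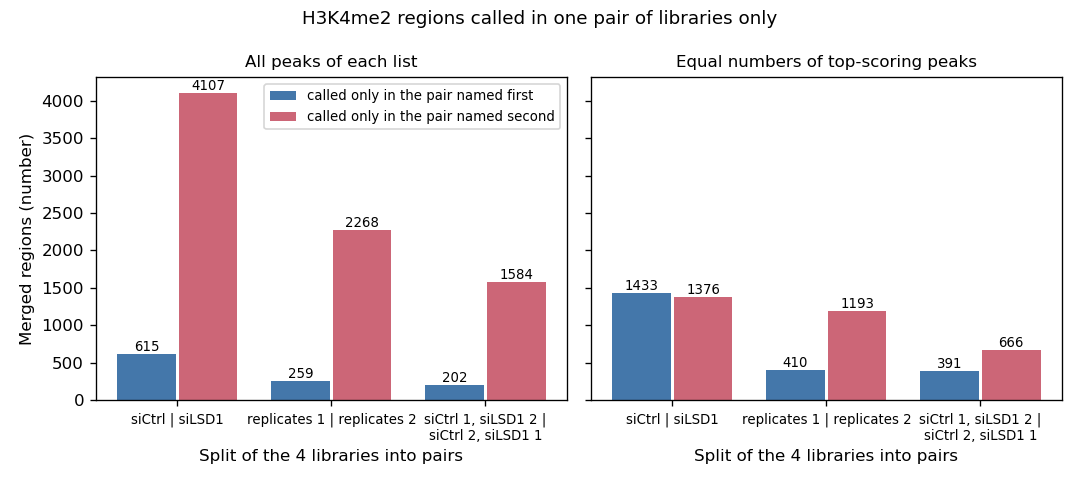
Bars give the number of merged H3K4me2 regions (vertical axis) called in both libraries of one pair and in neither of the other, for the 3 splits of the 4 libraries into pairs (horizontal axis), with all peaks on the left and 33878 peaks per list on the right. The siRNA split gave 4107 gained and 615 lost regions with all peaks, and 1376 gained and 1433 lost with equal numbers.

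**Figure D2:**
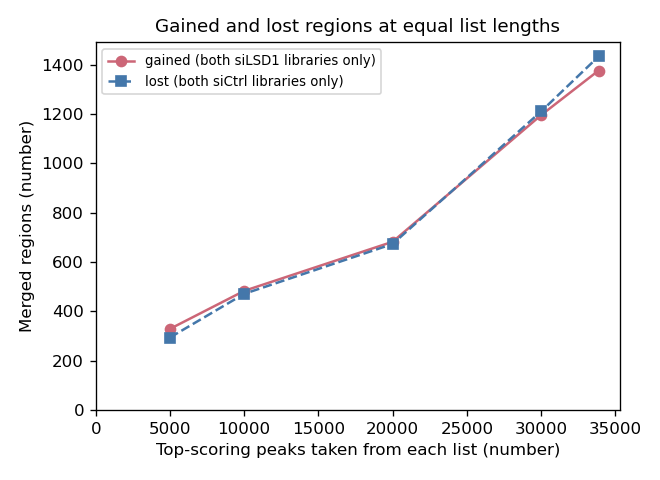
The points give the number of gained and lost regions (vertical axis) when the same number of top-scoring peaks (horizontal axis) was taken from each of the 4 library lists. Gained and lost regions stayed close at each length, from 329 and 294 with 5000 peaks to 1376 and 1433 with 33878 peaks.

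The regions with the highest pooled scores gave named examples. Of the gained regions, 3215 were also found only in the pooled siLSD1 list, and 387 of the lost regions only in the pooled siCtrl list. The gained region of highest pooled score lay in 19q13.32, at chromosome 19 from 47032117 to 47034448, with a pooled score of 1053.61 and scores of 625.59 and 780.64 in siLSD1 replicates 1 and 2. Next came 19p13.3 from 3317927 to 3321048, with a pooled score of 928.14, and 4p16.3 from 1605423 to 1607936, with 703.09. In 19p13.11 a gained region ran from 17514750 to 17518813 with a pooled score of 639.37. Chromosome 7 held gained regions in 7q32.3 from 131337449 to 131340391, in 7q11.23 from 73240917 to 73248210 and in 7p22.3 from 974554 to 977309, with pooled scores of 629.64, 628.69 and 594.41. In 19p13.2 a region from 13363257 to 13366870 had a pooled score of 621.2, and a neighbouring pair from 8633335 to 8635058 and from 8635079 to 8637094 shared a pooled peak with a score of 606.73. The remaining gained regions were in 9q32 from 116937230 to 116941134 and in 6q25.3 from 158033769 to 158037130, with pooled scores of 618.86 and 590.46.

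Among the lost regions, the highest pooled score was in 6p22.1. There, chromosome 6 from 28705571 to 28707113 had a score of 543.81 in the pooled siCtrl list and scores of 194.9 and 323.83 in siCtrl replicates 1 and 2. Chromosome 1 held lost regions in 1p22.1 from 94292391 to 94295465, in 1p36.13 from 19435995 to 19438226 and in 1p13.3 from 110077578 to 110079579, with pooled scores of 522.3, 516.54 and 407.19. A lost region in 20p13 ran from 1429118 to 1431032 with a pooled score of 448.42, and another in 8q21.13 from 81119196 to 81121713 with 362.73. Chromosome 17 held lost regions in 17q23.3 from 61394276 to 61395559 and in 17q21.2 from 38712576 to 38714504, with pooled scores of 340.45 and 322.85. The region in 16q24.2 from 87519795 to 87521696, with a pooled score of 355.55, lay 0.454 kb from a common region. Further lost regions were in 6q14.1 from 75944954 to 75946361, in 6q23.3 from 137336872 to 137338779 and in 15q26.2 from 94408351 to 94410894, with pooled scores of 329.27, 325.21 and 314.39. Whether these regions lie in genes was not analysed here, as no hg19 gene annotation was used.

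**Figure D3:**
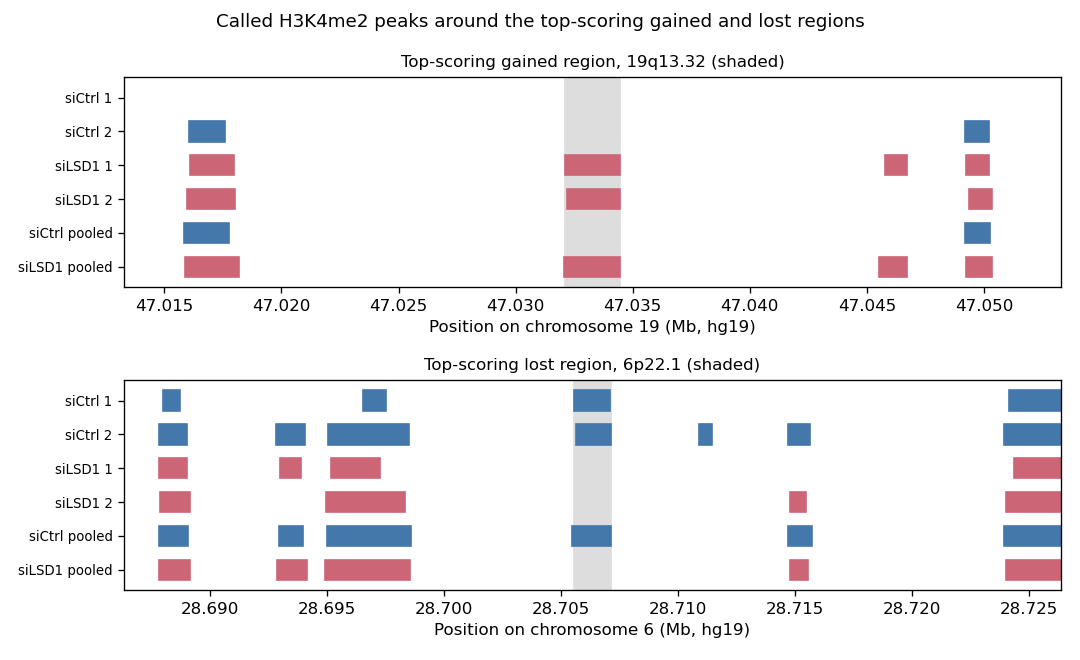
Boxes mark called H3K4me2 peaks along chromosomes 19 and 6 (horizontal axis, position in Mb on hg19), with a row for each library and pooled list, siCtrl in blue and siLSD1 in red, and the region shaded. In 19q13.32 both siLSD1 libraries and neither siCtrl library had a peak in the region from 47032117 to 47034448, and in 6p22.1 both siCtrl libraries and neither siLSD1 library had a peak in the region from 28705571 to 28707113.

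Gained and lost regions were spread unevenly over the chromosomes. On chromosome X, 24 of 1282 regions were gained (1.87%, exact 95% interval 1.203 to 2.77%) against 7.08% of regions elsewhere, with a Fisher's exact adjusted p of 1.13e-15. Chromosome 13 also had few gained regions, 40 of 1046 (3.82% against 7.02%, adjusted p = 0.000192), while chromosome 19 had many, 210 of 2408 (8.72% against 6.89%, adjusted p = 0.00365), and few lost ones, 10 regions (0.415% against 1.07%, adjusted p = 0.0216). Gained regions were also more frequent than elsewhere on chromosomes 2 (8.32%) and 7 (8.52%), and less frequent on chromosomes 5 (5.64%) and 6 (5.69%), with adjusted p of 0.000456, 0.00113, 0.0148 and 0.00748. With equal numbers of peaks the differences for gained regions on chromosomes 2, 5, 6 and 7 missed the threshold, with adjusted p of 0.253, 0.182, 0.842 and 0.0627. The shares were then 3.78% against 3.24% elsewhere on chromosome 2, 2.46% against 3.33% on chromosome 5, 3.16% against 3.30% on chromosome 6 and 4.19% against 3.23% on chromosome 7.

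With equal numbers of peaks, chromosome X had 2 gained regions among 936 (0.214% against 3.36%) and 66 lost regions (7.05% against 3.34%), with adjusted p of 5.37e-10 and 1.07e-06. The higher share of lost regions on chromosome X was called only with equal numbers, since with all peaks 15 of 1282 were lost (1.17% against 1.04%, Fisher's exact adjusted p = 0.793). On chromosome 19, 110 of 1996 regions were gained (5.51% against 3.18%) and 38 lost (1.90% against 3.50%), with adjusted p of 1.72e-06 and 0.000578. On chromosome 13, 8 of 720 were gained (1.11% against 3.33%, adjusted p = 0.00224) and 38 lost (5.28% against 3.39%, adjusted p = 0.0714). The cut to equal numbers removed the lowest-scoring peaks of the longer lists. Among regions called in all 4 libraries, the mean score percentile in each library was at most 38.5 on chromosome 13. It was at least 60.65 on chromosome 19, and chromosome X also ranked low. These values are of common regions and do not show where the peaks near the cut lay. If those peaks ranked alike, the cut can favour lost regions on chromosomes X and 13 and gained ones on chromosome 19. The adjusted p with equal numbers do not exclude this. With all peaks the gained share on chromosome X was 0.264 times that elsewhere. It was 0.285 times without siCtrl replicate 1, 0.685 times without siCtrl replicate 2, 0.661 times without siLSD1 replicate 1 and 0.348 times without siLSD1 replicate 2. The same chromosomes also stood apart in the split by replicate number. There, with equal numbers of peaks, regions found only in replicates 2 made up 6.41% of those on chromosome X against 2.77% elsewhere, 6.25% against 2.79% for chromosome 13, and 1.15% against 2.94% for chromosome 19.

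**Figure D4:**
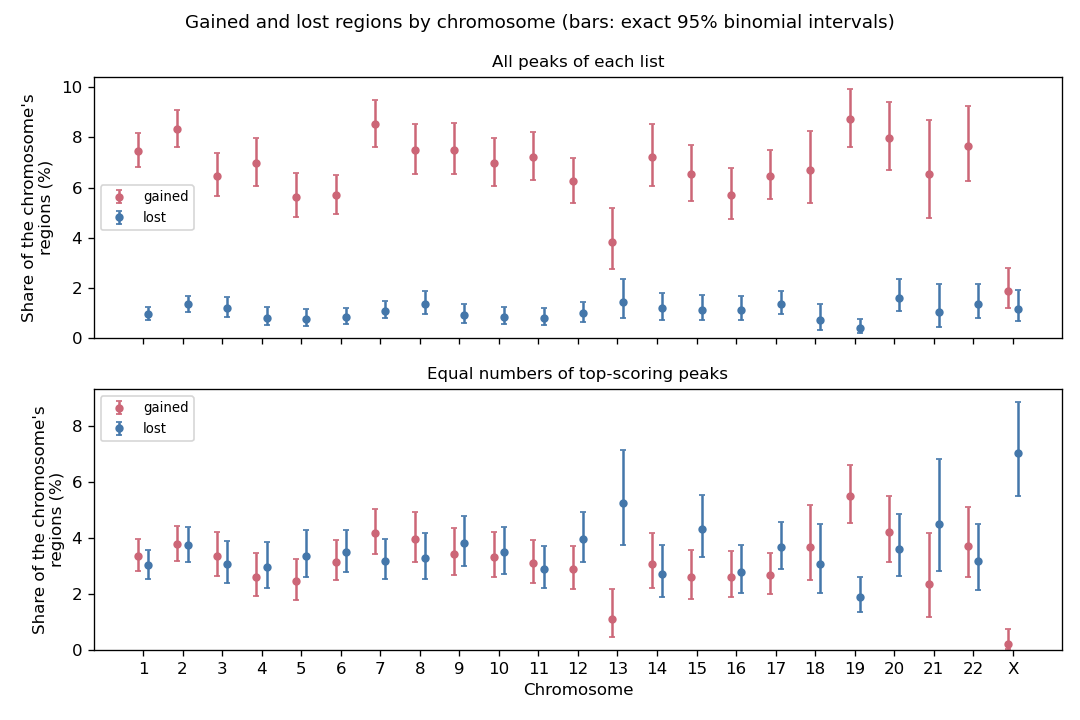
Points give gained and lost regions as a share of each chromosome's regions (vertical axis, percent) by chromosome (horizontal axis), with exact 95% binomial intervals as bars, for all peaks above and equal numbers of peaks below. Chromosome X had the lowest share of gained regions in both panels, 1.87% and 0.214%.

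Among 489 cytobands with at least 50 regions, gained regions were more frequent in 19p13.3, with 59 of 484 (12.2% against 6.92% elsewhere, Fisher's exact adjusted p = 0.00764). They were less frequent in 17p11.2, with 0 of 174 (upper 95% limit 2.10%, adjusted p = 0.00353), and in Xq28, with 0 of 145 (upper limit 2.51%, adjusted p = 0.00837), which is part of the chromosome X result. As on chromosome X, common regions of 17p11.2 ranked lower in both siLSD1 libraries than in both siCtrl libraries. Their mean score percentiles were 34.6 and 39.0 after siLSD1 and 43.8 and 42.4 after siCtrl. In lists of equal length, where single bands were not tested, 19p13.3 had 31 of 406 regions gained (7.64%) and 5 lost, 17p11.2 had 1 of 141 gained and 6 lost, and Xq28 had 0 of 124 gained and 10 lost (8.06%). For lost regions 0 of the 489 bands passed Fisher's exact test after adjustment, the smallest adjusted p being 0.346. An unadjusted p under 0.05 was found for 28 of them. How many chance would give, with so few lost regions per band, was not computed.

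The third comparison asked in which windows of the genome the breadth of the mark changed. Of 57558 10-kb windows with a peak, 3511 had peaks in both siLSD1 libraries only and 529 in both siCtrl libraries only. With equal numbers of peaks these were 1404 and 1288 windows. The gained count was 4007 without siCtrl replicate 1, 10071 without siCtrl replicate 2, 7731 without siLSD1 replicate 1 and 6999 without siLSD1 replicate 2, and the lost counts in that order were 3277, 1143, 1214 and 1317. In the limma test of covered kilobases over 43372 windows, 0 were higher and 0 lower after adjustment, and the smallest adjusted p was 0.129. At an unadjusted p under 0.05, limma had 5389 windows higher and 840 lower after siLSD1. Simulated unchanged windows had a p under 0.05 in 5.81% of cases. The simulation had independent noise in each window and no difference in list length, so this is not the rate expected of these lists. The balance moved to 2608 and 1627 with equal numbers of peaks, when 34544 windows were tested, 4202 and 1776 with quantile normalization, 3310 and 1092 without siCtrl replicate 1, and 8772 and 506 without siCtrl replicate 2. The median window had 0.213 kb more under peaks after siLSD1, 0.0295 kb more without siCtrl replicate 1, 0.452 kb more without siCtrl replicate 2, and -0.102 kb with quantile normalization. The test called 0 of 100 simulated windows shifted by 2 kb, so that changes of this size in single windows were not detectable with 2 libraries per group.

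The pooled lists, which the submitters used for their final analysis, differed in the same direction as the full library lists. Of 56860 peaks in the pooled siLSD1 list, 15364 (27.0%, exact 95% interval 26.7 to 27.4%) overlapped no peak of the pooled siCtrl list. Of 45219 peaks in the pooled siCtrl list, 4008 (8.86%, 8.60 to 9.13%) overlapped none of the pooled siLSD1 list, a ratio of 3.83. Peaks found in the pooled siLSD1 list only had a median width of 1257 bp and a median score of 85.9, against 2199 bp and 416.56 for shared peaks. Both siLSD1 libraries and neither siCtrl library had a peak at 3232 (21.04%) of the peaks found only after siLSD1, while 3886 were in none of the library lists and 1587 overlapped a peak of a siCtrl library. For the peaks found only after siCtrl, 390 (9.73%) had both siCtrl libraries and neither siLSD1 library behind them, 1209 were in none of the library lists and 588 overlapped a peak of a siLSD1 library. With equal numbers of peaks, 45219 from each pooled list, 4651 were found only after siLSD1 and 4879 only after siCtrl. The pooled lists have no replicates, and no test was run on them.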

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

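Single libraries set against each other, shorter equal lists, lists without chromosome X, 5-kb and 25-kb windows, and list totals without 1 library were chosen after seeing the data; all other alternatives were fixed before the data were examined. The differences in peak number and covered length between the siRNA groups kept their sign under all alternatives run, at 5268 to 16221 peaks and 6.54 to 30.5 Mb without 1 library. Leaving out 1 library could not turn either sign, since both siLSD1 lists were longer and covered more sequence than both siCtrl lists. Nor could the upper 50% turn that of peak number. Covered length was not compared with equal numbers of peaks. The counts of gained and lost regions stayed within 1.5 times with a 50% overlap (4147 and 634), with gaps up to 1000 bp merged (3662 and 535) and without chromosome X (4083 and 600). Read depth is unknown, so how far it sets the list lengths was not tested.

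Equal numbers of peaks gave 1376 gained and 1433 lost regions, a ratio of 0.960. The top 10000, 20000 and 30000 peaks gave 483, 682 and 1195 gained and 471, 673 and 1210 lost regions, with ratios of 1.03, 1.01 and 0.988. The upper 50% of each list gave 1780 and 196. Fewer peaks enter in each of these by construction. Without 1 library, the counts ranged from 4607 to 10861 gained and from 1351 to 4079 lost, and the ratio from 1.13 without siCtrl replicate 1 to 7.82 without siCtrl replicate 2. Leaving out a library loosens the rules, so that both counts rise by construction, but this does not fix which way the ratio moves.

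In the pooled lists, peaks found only after siLSD1 and only after siCtrl numbered 6580 and 1144 in the upper 50% (ratio 5.75), and 4651 and 4879 with equal numbers (ratio 0.953). With support by both own replicates and none of the other group they numbered 3232 and 390 (ratio 8.29). In 10-kb windows, gained and lost counts were 1977 and 234 in the upper 50%, 1404 and 1288 with equal numbers, and 12286 and 3376 in the pooled lists. Without 1 library they ranged from 4007 to 10071 and from 1143 to 3277.

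The limma test of breadth gave 0 windows higher and 0 lower in all alternatives run except quantile normalization, with 3 higher and 2 lower and a median change of -0.102 kb, where the cause was not tested. The median change was 0.0965 kb with equal numbers, 0.32 kb in 25-kb windows, and 0.0295 to 0.452 kb without 1 library, when the lone library was assumed to vary like the other group. The share of gained regions in light-staining bands was 57.5% in the upper 50% and ranged from 53.7% to 55.7% without 1 library, and that of lost regions ranged from 50.7% to 58.1%.

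Whether the replicate numbers pair the libraries is not given by the labels, and 2 pairs are too few to show it. The correlation across windows of the deviations of siCtrl replicate 1 and siLSD1 replicate 1 from their group means was 0.150. With replicate number as a block, limma again called 0 windows higher and 0 lower, with a median change of 0.213 kb. The region counts under the block were 4107 and 615, and the window counts 3511 and 529, the same by construction. Not run, because no hg19 annotation was used here, were the alternatives of the gene list tests, the wider promoter window and the narrower window around transcription start sites.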

Other observations

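Of the tests here, the 20 cytobands, the tests of the excess of gained regions and the test of chromosome X in the replicate split were chosen after the data were seen. The patterns tested on chromosome X and near common regions were themselves found in these libraries. In 6 groups of bands that carry well-known genes, the shares of gained and of lost regions did not pass the test against the rest of the genome, with all peaks or with equal numbers of peaks. These bands hold many other genes, so the values are those of bands. In the 4 bands of the HOX homeobox clusters, 33 of 598 regions were gained (5.52% against 6.98% elsewhere, Fisher's exact adjusted p = 0.691) and 8 were lost. The balance turned with equal numbers of peaks, to 9 gained and 13 lost (adjusted p = 0.528 and 0.877). In 7 bands known for adhesion and matrix genes, such as 5q31.3 with the clustered protocadherins, 16q22.1 with E-cadherin and 21q22.3 with collagen VI genes, 52 of 883 regions were gained (5.89% against 6.98%, adjusted p = 0.691) and 12 were lost (1.36% against 1.04%, adjusted p = 0.625). It turned here too with equal numbers, to 11 gained (1.68% against 3.31%, adjusted p = 0.116) and 27 lost (4.13% against 3.41%, adjusted p = 0.877). The turn was not particular to these groups, since over the genome the counts went from 4107 gained and 615 lost to 1376 and 1433. In 3 bands of muscle genes, among them 11p15.1 with MYOD1 and 1q32.1 with MYOG, 44 of 612 regions were gained (7.19% against 6.96%, adjusted p = 0.870) and 5 lost, and 17 were gained and 16 lost with equal numbers. The 3 bands of genes of other lineages, with globin, keratin and albumin genes, had 25 of 347 regions gained (7.20%, adjusted p = 0.870) and 2 lost, and 8 gained and 10 lost with equal numbers. The bands of MYC and MYCN had 12 of 199 gained (6.03%, adjusted p = 0.870) and 4 lost, and 3 gained and 8 lost with equal numbers, while the band of KDM1A had 9 of 144 gained (6.25%, adjusted p = 0.870) and 0 lost, and 5 gained and 2 lost with equal numbers.

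In 8q24.21, the band of MYC, covered length was 159 and 284 kb in the siCtrl libraries and 392 and 283 kb in the siLSD1 libraries. The replicates thus lay far apart within both siRNA groups. In 18q12.1, the band of the desmosomal cadherin genes, it was 59.3 and 95.1 kb after siCtrl and 106 and 118 kb after siLSD1. As a share of each list's covered length this band was higher in both siLSD1 libraries than in both siCtrl libraries, at 1.10 and 1.13 per mille against 0.846 and 1.01 per mille. Other bands of the adhesion group went the other way on this share, 16q22.1 with E-cadherin at 3.79 and 3.47 per mille after siCtrl and 3.29 and 3.36 after siLSD1, and 2q32.2 with collagen genes at 1.98 and 2.03 against 1.93 and 1.95. Of the 20 bands, 3 were higher in this way (18q12.1, 11q22.2 and 1p36.12) and 5 lower (16q22.1, 2q32.2, 7p15.2, 17p13.1 and 17q21.2). Libraries with no systematic difference would give 16.7% each. The widest region of all lay in 1q42.13, the band of the 5S ribosomal RNA gene array, at chromosome 1 from 228743619 to 228785341. It was a single peak of 41.4 kb in siCtrl replicate 2 and of 41.7 kb in siLSD1 replicate 2, with 0 peaks in both replicates 1, and it was in the pooled siLSD1 list but had 0 peaks in the pooled siCtrl list.

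The excess of gained over lost regions may come from the lengths of the lists. With equal numbers of peaks per list the ratio was 0.960. Of the 1433 regions lost in those lists, only 264 were also lost with all peaks, so this ratio does not settle the source of the excess. Whether the short list of siCtrl replicate 1 is enough to account for it stays open, because siCtrl replicate 2 against 1 siLSD1 library at a time still gave ratios of 1.35 and 1.61, against 7.24 and 7.81 for siCtrl replicate 1. A rise of the mark over the whole genome after the siRNA against LSD1 cannot be told apart from longer lists, because both siLSD1 lists were longer. The exact permutation p of covered length, 0.333, is the smallest that 2 libraries against 2 allow. Equal list lengths would also remove such a rise.

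Chromosome X had few gained regions also with equal numbers of peaks, at 0.0636 times the share of other chromosomes (95% interval 0.0159 to 0.254). This does not exclude a part of the list lengths. Equal numbers drop the lowest-scoring peaks of the longer lists, and common regions on X ranked low in the siLSD1 libraries. Where the X peaks near the cut ranked was not examined. Among regions called in all 4 libraries, the mean score percentile of X regions was 33.4 and 36.9 in the siCtrl libraries and 24.1 and 28.1 in the siLSD1 libraries, a gap of 5.26 between the nearest libraries, as a lower signal over the whole chromosome in the siLSD1 libraries would give. Variation of chromosome X between libraries apart from the siRNA may contribute, since in the split by replicate number the share of X regions found only in replicates 2 was 2.32 times that elsewhere (1.80 to 2.98). An effect of LSD1 on chromosome X stays open, and so does a difference in copy number between cultures, for which the input libraries would be needed.

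Gained regions lay near common regions more often than lost ones, as a spread of marked domains into their flanks might give. The ratio of the shares within 5 kb was 1.19 with all peaks (95% interval 1.01 to 1.40). With equal numbers of peaks the ratio was 1.23 (1.07 to 1.43). This does not exclude list length as the source, because equal numbers cut only the longer lists by score. Gained regions were then wider than lost ones, with medians of 1807 and 1487 bp. Whether libraries also differ in this way apart from the siRNA cannot be told apart, because the ratio in the split by replicate number, replicates 2 to replicates 1, was 0.824 with an interval of 0.660 to 1.03. The spread of domains is a hypothesis found and tested on the same libraries.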
